A study of Homo sapiens with 3 samples.

How the data were processed

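Poly(A)-selected RNA from THP-1 cells, a human acute monocytic leukaemia line, was sequenced in 3 libraries. One library came from untreated cells and the others from cells exposed to FL-Fc-DM1 at 1 nM or 3 nM for 1 day. Each group held 1 library, so the libraries carry no replicates.

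The authors deposited 1 table of 20332 genes with Ensembl identifiers, gene symbols, and KEGG and Gene Ontology annotation. Per the file headers, the table gives a count column and a TPM column for each library. The deposited counts are estimated counts: between 12.1% and 13.2% of the values of a library were not whole numbers. The deposited TPM values summed to 1000000 in each library. Per the submitters' processing notes, fastp 0.18.0, HISAT2, StringTie 1.3.1, DESeq2 and edgeR were used, with no role or order stated. The genome build, the gene annotation and the strand setting are not given in the sources used here, so genes are identified by symbol and Ensembl identifier and no coordinates are printed. Estimated counts divide reads between overlapping or near-identical genes, so values of readthrough models, paralogs and antisense partners are uncertain.

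The sample columns carry the numbers 0, 1 and 2 after the name of the agent. They were read as dose levels, 0 for the control, 1 for 1 nM and 2 for the second dose, 3 nM. This is a reading of the names and not a statement in the labels, and every direction between libraries rests on it. No column of sample values was left unused.

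The counts summed to 20817408 in the control library, 20417769 at 1 nM and 17747893 at 3 nM. Rows without a gene symbol numbered 617 and held 0.159%, 0.166% and 0.163% of the counts in that order. They stayed in the library totals and in the counts of genes. Of the identifiers in the table, 20304 were found in a reference table of gene names.

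Counts were scaled to CPM, counts for every 1000000 in a library, on library sizes adjusted by the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3. For CPM and for intervals the counts were rounded to whole numbers. The TMM factors were 1.00 in the control library, 0.999 at 1 nM and 0.999 at 3 nM. Differences between libraries are differences of log2(CPM + 1), which understate the change of genes with low values. Genes with a mean of at least 1 CPM over the 3 libraries were examined, which left 11908 genes. At this level 1 CPM stood for 17.7 to 20.8 counts.

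No test between conditions was possible with 1 library per group, so no p-value is given and differences have no replicate check. Genes were counted by size alone, as at least 2-fold apart, which is a log2 difference of 1 or more in either direction. The ratio of the CPM values of a gene is given with a 95% exact (Clopper-Pearson) conditional interval of the counts. Such intervals cover counting error only, because PCR copies are not independent molecules and the variation between cultures is not measured. They compare libraries, not conditions.

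The 31 gene lists and the rule for naming genes were fixed before the data were examined, as were the size rule and all but 2 of the alternatives below. The lists held 823 entries for distinct genes, of which 635 passed the expression filter. For the 29 lists with at least 5 measured members, the median log2 difference was set against the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these libraries and is not a p-value. The range of random lists quoted is that between the 2.5th and 97.5th percentiles. Some genes stand on more than 1 list.

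Genes were named by a rule. For each pair of libraries it took the 8 genes with the highest and the 8 with the lowest log2 difference among symbols with a mean of at least 5 CPM, leaving out clone, LOC, pseudogene-style and antisense names and keeping those past 2-fold. From each list it took up to 4 measured members with the largest absolute difference at 3 nM. It added 18 genes chosen in advance for the agent and the cells. The rule named 139 genes. Genes outside it are marked as chosen after their values were seen.

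Both doses were compared with the same control library. To show what this alone produces, 3 libraries without any difference were drawn 100 times from the mean of each gene, with Poisson counts and again with an added variation of 10% between libraries. Medians of the lists were taken in 100 further draws of each kind, a step added after the list medians were seen. The added variation was drawn for each gene alone. The procedure was tested on simulated data made from the real means and library sizes of 20332 genes, with 200 genes changed. In the simulated 1 nM and 3 nM comparisons with the control, the size rule found 100% of 50 genes raised 4-fold at both doses, 94% and 98% of 50 genes lowered to 0.25 of the control, and 0% of 50 genes raised 1.3-fold. Of 11703 unchanged genes, 0% were called higher or lower. The counting intervals held the true ratio for 95.2% and 95.6% of all genes that passed the filter, changed genes included. These were Poisson draws, so this shows only that the intervals cover counting error.

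The alternatives were the library total or DESeq2 1.42.0 size factors in place of TMM, TPM in place of CPM, a pseudocount of 0.1 or 5, no filter or a mean of at least 10, 1.5-fold in place of 2-fold, and the mean of a list in place of its median. Thinning to equal depth and removing trends with transcript length and GC content (lengths and GC content from GENCODE release 29, which may differ from the annotation the authors used) were added after the data were seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.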

Results

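Gene expression was measured in THP-1 cells, an established human monocytic leukaemia line, left untreated or exposed for 1 day to FL-Fc-DM1. The labels do not describe the agent. From its name it joins FL, read here as FLT3 ligand, to an Fc part and DM1, a maytansinoid that binds tubulin and blocks microtubule assembly. The study asked how the transcriptome of the cells differed between the groups. There was 1 library for the control, 1 for 1 nM and 1 for 3 nM, with 20817408, 20417769 and 17747893 counts, and 14899, 15039 and 14778 genes with at least 1 count. Without replicates, every difference below is between single libraries, and the intervals are 95% exact counting intervals that leave out variation between cultures. Assignment of the doses to the columns of the deposited table is a reading of the column names.

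Compared with the control, the 1 nM library had higher levels of NF-kB target and inflammatory cytokine genes, interferon-stimulated genes and the listed G2/M genes, and lower levels of the listed genes of DNA replication. The NF-kB inhibitor gene TNFAIP3 (ENSG00000118503) stood at 14.01 CPM in the control and 82.4 CPM at 1 nM, a ratio of 5.89 (interval 5.19 to 6.69). The cytokine gene IL1B (ENSG00000125538) stood at 11.3 and 38.9 CPM, a ratio of 3.43 (2.97 to 3.99). CCNE2 (ENSG00000175305), which encodes cyclin E2 of the G1/S transition, stood at 104 and 31.3 CPM, 3.33-fold lower (3.05 to 3.64). In all, 89 genes were at least 2-fold higher and 26 at least 2-fold lower among 11908 genes.

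Among the NF-kB and inflammatory cytokine genes, 13 of 24 measured members were at least 2-fold higher at 1 nM and 0 were at least 2-fold lower, with a median log2 difference of 1.19, above all 10000 matched random lists. NFKB2, a subunit gene of NF-kB, stood at 9.12 CPM in the control and 38.6 CPM at 1 nM. The adhesion molecule gene ICAM1 stood at 2.495 and 13.6 CPM, and the chemokine gene CXCL8 at 28.6 and 71.4 CPM. IL18 was the 1 member below 0, at -0.03. The size of the list median depended on the settings, at 0.73 with a pseudocount of 5, 0.75 without a filter, 1.38 with a pseudocount of 0.1 and 1.42 among members with a mean of at least 10 CPM.

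The interferon-stimulated genes had a median of 0.45 at 1 nM, with 4 of 26 members at least 2-fold higher and 20 of 26 above 0. These included IFIH1, a sensor of double-stranded RNA, at 9.74 CPM in the control and 27.0 CPM at 1 nM, and the antiviral gene OAS2 at 14.5 and 33.6 CPM. The median lay above all 10000 random lists, and was 0.13 among members with a mean of at least 10 CPM.

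All 43 G1/S and DNA replication genes had lower values at 1 nM than in the control. Of these, 6 were at least 2-fold lower, and the list median of -0.70 lay below all 10000 random lists. PCNA, the sliding clamp of DNA polymerases, stood at 189 CPM in the control and 91.1 CPM at 1 nM, the exonuclease gene EXO1 at 112 and 43.2 CPM, and the uracil-DNA glycosylase gene UNG at 82.8 and 32.4 CPM. In the same libraries the G2/M and mitosis genes had a median of 0.43, above all 10000 random lists, with 43 of 47 above 0 and 2 at least 2-fold higher. The 416 other genes annotated to mitosis or cell division had a median of 0.00526 at 1 nM, inside the range, with 213 above 0 and 203 below. The rise of the listed genes thus did not extend to these other genes as a set. Every listed gene is left out of this set, so its median says nothing against the rise of the listed genes. CCNB1, the gene of mitotic cyclin B1, stood at 198 and 412 CPM, a ratio of 2.08 (2.00 to 2.16). The proliferation marker gene MKI67 stood at 966 and 982 CPM, a ratio of 1.02 (0.997 to 1.04).

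The 8 named genes with the highest differences at 1 nM also held genes outside these lists. IL4I1, which encodes an amino acid oxidase of myeloid cells, stood at 0.72 CPM in the control and 10.2 CPM at 1 nM, a log2 difference of 2.71 that was 1.41 with a pseudocount of 5. C3AR1, the complement C3a receptor gene, stood at 3.65 and 26.6 CPM, a ratio of 7.29 (5.72 to 9.39). The sulfotransferase gene CHST2 stood at 4.365 and 24.0 CPM, and the glucose transporter family gene SLC2A6 at 4.365 and 22.7 CPM. At the other end, ATP1B1, a subunit gene of the sodium pump, stood at 12.1 and 3.97 CPM, MAP2K6, a kinase gene of the p38 pathway, at 14.7 and 5.10 CPM, and E2F7, a repressor of the E2F family, at 41.5 and 17.3 CPM.

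The counting interval of the ratio excluded 1 for all 89 higher and all 26 lower genes at 1 nM. The size rule selects on the same counts, so this follows almost from the selection and adds no support. Libraries simulated without any difference gave a mean of 0.02 higher and 0 lower genes with Poisson counts. With an added 10% variation between libraries the means were 0.09 and 0.05, but the real variation between cultures was not measured. The counts depended on the rule, with 29 higher and 8 lower genes at a pseudocount of 5 and 336 and 267 at 1.5-fold.

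**Figure D1:**
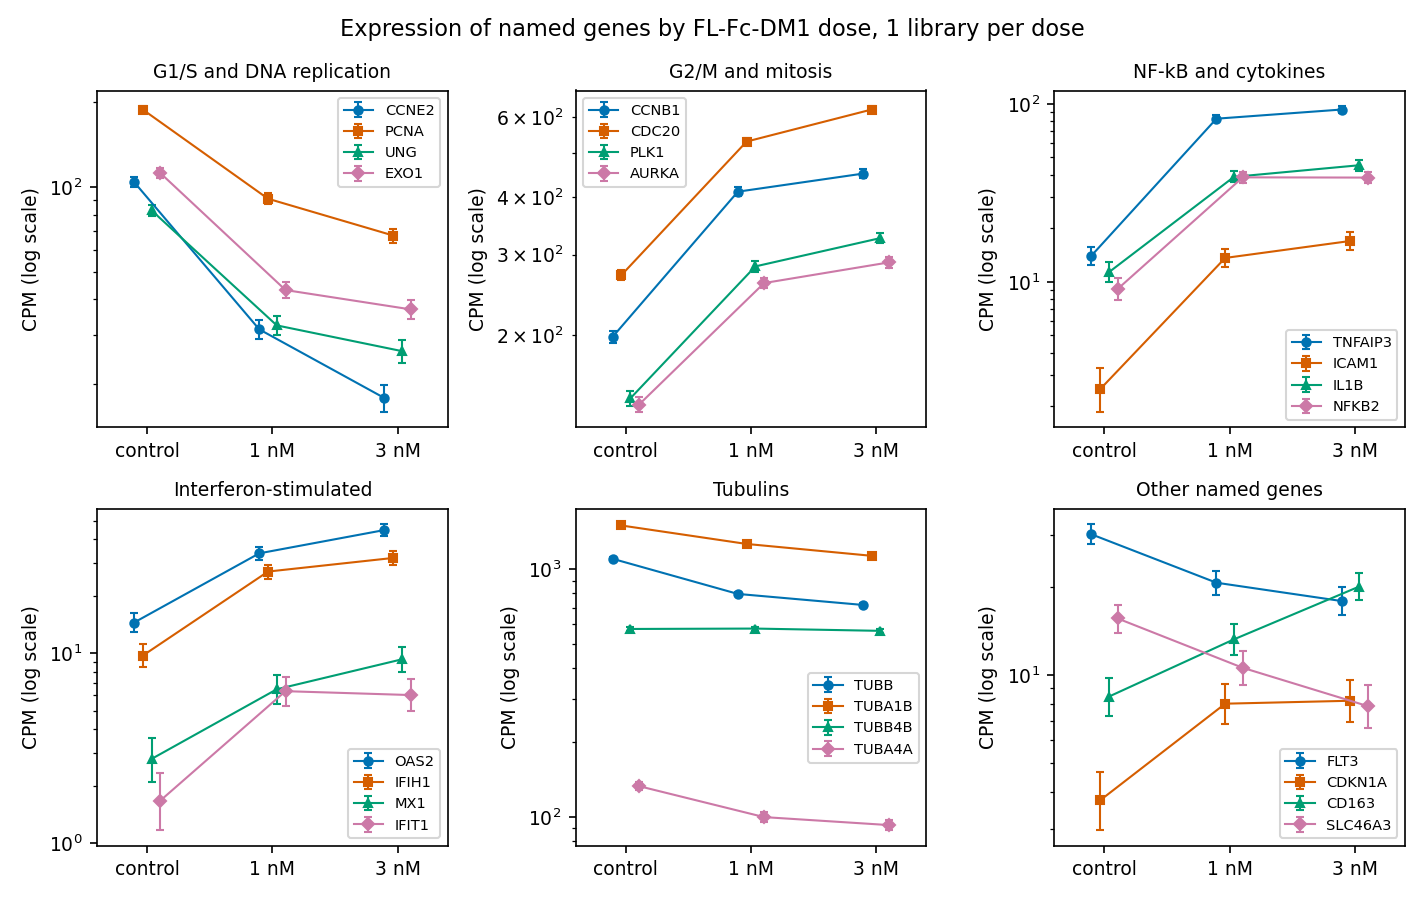
Expression in CPM on a log axis of 24 named genes in the control, 1 nM and 3 nM libraries, 1 library each, with lines joining a gene and bars for the 95% exact Poisson interval of its count. CCNE2 went from 104 to 31.3 and 17.9 CPM and TNFAIP3 from 14.01 to 82.4 and 92.8 CPM, while TUBB4B stayed between 565 and 577 CPM.

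At 3 nM the same groups stood apart from the control. CCNE2 stood at 17.9 CPM, 5.84-fold below the control (5.19 to 6.59), and PCNA at 67.4 CPM, 2.80-fold below (2.62 to 2.99). TNFAIP3 stood at 92.8 CPM, a ratio of 6.62 (5.85 to 7.53), and IL1B at 45.2 CPM, a ratio of 3.99 (3.45 to 4.63). A total of 110 genes were at least 2-fold higher and 69 at least 2-fold lower.

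All 43 G1/S and DNA replication genes were again below the control at 3 nM, 15 of them at least 2-fold, with a median of -0.80 that lay below all 10000 random lists. EXO1 stood at 36.9 CPM and UNG at 26.2 CPM. Outside the list, FAM111B, a protease gene, stood at 16.3 CPM in the control and 2.48 CPM at 3 nM, WDR76 at 94.2 and 28.9 CPM, and E2F7 at 41.5 and 11.4 CPM.

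The G2/M and mitosis genes had a median of 0.52, above all 10000 random lists, with 5 of 47 at least 2-fold higher. Among these were CDC20, an activator of the anaphase-promoting complex, at 271 CPM in the control and 623 CPM at 3 nM, and the mitotic kinase genes PLK1 at 145 and 326 CPM and AURKA at 141 and 288 CPM. CCNB1 stood at 451 CPM, and MKI67 at 1024 CPM, a ratio of 1.06 (1.04 to 1.08).

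The NF-kB list had a median of 1.16 at 3 nM, again with 13 of 24 members at least 2-fold higher and above all 10000 random lists. ICAM1 stood at 16.97 CPM, NFKB2 at 38.5 CPM and CXCL8 at 65.1 CPM. The median was 0.73 with a pseudocount of 5, 0.78 without a filter, 1.36 with a pseudocount of 0.1 and 1.51 among members with a mean of at least 10 CPM. The interferon list had a median of 0.56 with 5 of 26 members at least 2-fold higher, among them OAS2 at 44.6 CPM, IFIH1 at 31.8 CPM, the antiviral GTPase gene MX1 at 2.78 CPM in the control and 9.30 CPM at 3 nM, and IFIT1 at 1.68 and 6.03 CPM. Among members with a mean of at least 10 CPM this median was 0.16.

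Tubulin genes, whose products DM1 binds, differed among themselves. TUBB (ENSG00000196230) stood at 1104, 796 and 718 CPM in the control, 1 nM and 3 nM libraries, 1.54-fold below the control at 3 nM (1.503 to 1.57). TUBA1B stood at 1505, 1267 and 1135 CPM, and TUBA4A at 133, 99.8 and 92.7 CPM. TUBB4B stood at 575, 577 and 565 CPM, a ratio of 0.983 at 3 nM (0.957 to 1.01). TUBB2A stood at 1.87, 2.45 and 1.75 CPM, and TUBB3 at 1.63, 2.26 and 3.27 CPM. As a list the 10 measured tubulin genes had medians of -0.01 and -0.13, inside the range of random lists at both doses, and 0 members were 2-fold apart. Among members with a mean of at least 10 CPM, which leaves out TUBB2A and TUBB3, the medians were -0.12 and -0.22. Reads shared between tubulin paralogs and pseudogenes make these values uncertain. The 27 microtubule-associated and stathmin genes had medians of 0.04 and 0.02, inside the range, with means of -0.01 and -0.00.

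FLT3, the receptor gene of FLT3 ligand, stood at 30.2 CPM in the control, 20.6 CPM at 1 nM and 17.9 CPM at 3 nM, 1.69-fold below the control at 3 nM (1.47 to 1.94). The list of FLT3 and MAPK feedback genes had medians of 0.30 and 0.32, above all 10000 random lists, with 2 of 21 members at least 2-fold higher at each dose. These members were the early response transcription factor gene EGR1, at 9.07, 21.9 and 21.9 CPM, and PHLDA1, at 3.84, 8.97 and 10.6 CPM. The immediate early genes had medians of 0.39 and 0.37, above all 10000 random lists. JUN stood at 2.78, 6.52 and 5.69 CPM and FOS at 28.6, 37.4 and 37.5 CPM.

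Several other lists lay above the range of random lists at both doses by smaller amounts. The MYC and ribosome biogenesis genes had medians of 0.21 and 0.20 and means of 0.21 and 0.26, with the RNA helicase gene DDX21 at 483, 734 and 771 CPM. The heat shock proteins had medians of 0.16 at both doses (means 0.24 and 0.24), the ATF4 and unfolded protein response genes 0.12 and 0.13 (means 0.18 and 0.17), and the MHC class I and antigen processing genes 0.19 and 0.26. TRIB3, a stress-induced pseudokinase gene of the ATF4 pathway, stood at 51.4, 97.2 and 114 CPM, the chaperone gene HSPA5 at 822, 1022 and 1032 CPM, and DDIT3 at 11.5, 13.969 and 12.5 CPM. The monocyte and macrophage genes had medians of 0.12 and 0.13, with means of 0.22 and 0.29, and the dendritic cell genes 0.29 and 0.26, which were 0.13 and 0.10 without a filter. The scavenger receptor gene CD163 stood at 8.44, 13.2 and 20.01 CPM, and CD14 at 1.25, 1.57 and 2.42 CPM. The efflux transporters had medians of 0.18 and 0.17, above the range at 1 nM and inside it at 3 nM, with means of 0.06 and -0.01. SLC46A3, a lysosomal transporter gene that carries maytansinoid catabolites, stood at 15.6, 10.6 and 7.84 CPM, 1.99-fold below the control at 3 nM (1.63 to 2.44). ABCB1, the drug efflux pump gene, stood at 0.05, 0.24 and 0.40 CPM, from 1, 5 and 7 counts, below the expression filter. The interval of its ratio was 0.572 to 242 at 1 nM and 1.06 to 371 at 3 nM. With so few counts no direction is read from it.

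The p53 target genes had medians of 0.06 and 0.10, inside the range of random lists. Within the list CDKN1A, the p21 gene, stood at 3.74, 7.99 and 8.18 CPM, a ratio of 2.18 at 3 nM (1.65 to 2.92), while ZMAT3 stood at 28.5, 16.03 and 11.8 CPM and GADD45A at 3.50, 3.97 and 4.06 CPM. The apoptosis regulators had medians of 0.06 and 0.02, inside the range, and means of 0.13 and 0.11, with 2 of 29 members at least 2-fold higher at each dose. These were BIRC3, at 1.25, 7.06 and 5.75 CPM, and BCL2A1, at 2.30, 7.60 and 7.10 CPM, both survival genes downstream of NF-kB. The gasdermin and inflammasome genes had medians of -0.04 and 0.01 and means of 0.09 and 0.08.

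Medians inside the range of random lists at both doses were also found for the SRF and MRTF targets (0.06 and 0.05), Fc receptor genes (0.07 and 0.06, with means of 0.34 and 0.31), MHC class II genes (-0.01 and -0.02), cholesterol biosynthesis (-0.05 and -0.03, with means of -0.00 and -0.01), glycolysis (-0.08 and -0.01, with means of 0.05 and 0.06), lysosome and autophagy (-0.01 and 0.01, with means of 0.04 and 0.07) and replication-dependent histone genes (0.34 and 0.08). Only 5 of 45 histone genes were measured, too few to stand for that list. Within these lists the Fc receptor gene FCAR stood at 3.45, 11.4 and 12.3 CPM, and CIITA, the transactivator of MHC class II genes, at 9.498, 7.205 and 3.61 CPM. The cytosolic ribosomal protein genes had medians of -0.03 and -0.07, mitochondrially encoded transcripts -0.06 and -0.13 and nuclear oxidative phosphorylation genes 0.00 and -0.07, each inside the range at 1 nM and below it at 3 nM. Markers of other cells were few. The granulocyte, erythroid and megakaryocyte list, led by PRTN3 and CTSG, which these cells expressed at 517 and 215 CPM in the control, had medians of -0.25 and -0.19, below the range at 1 nM and inside it at 3 nM. The lymphoid list had 2 of 20 members measured, with medians of 0.33 and 0.21, and the epithelial and fibroblast list 2 of 15, with medians of 0.19 and 0.23.

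The counting interval excluded 1 for all 110 higher and all 69 lower genes at 3 nM. As at 1 nM, this follows almost from the selection. Simulated unchanged libraries gave means of 0.01 and 0.02 genes with Poisson counts, and 0.07 and 0.2 with an added variation of 10%. Of the list medians outside their ranges, 11 of 14 at 1 nM and 11 of 15 at 3 nM lay beyond all 100 draws with that added variation. Those within the draws were the MHC class I, monocyte and macrophage, and efflux lists at 1 nM, and the heat shock, ribosomal protein, mitochondrially encoded and nuclear oxidative phosphorylation lists at 3 nM. The added variation was drawn for each gene alone, so these draws do not cover a shift of a whole list between cultures. A pseudocount of 5 gave 42 and 29 genes, and 1.5-fold gave 421 and 470.

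**Figure D2:**
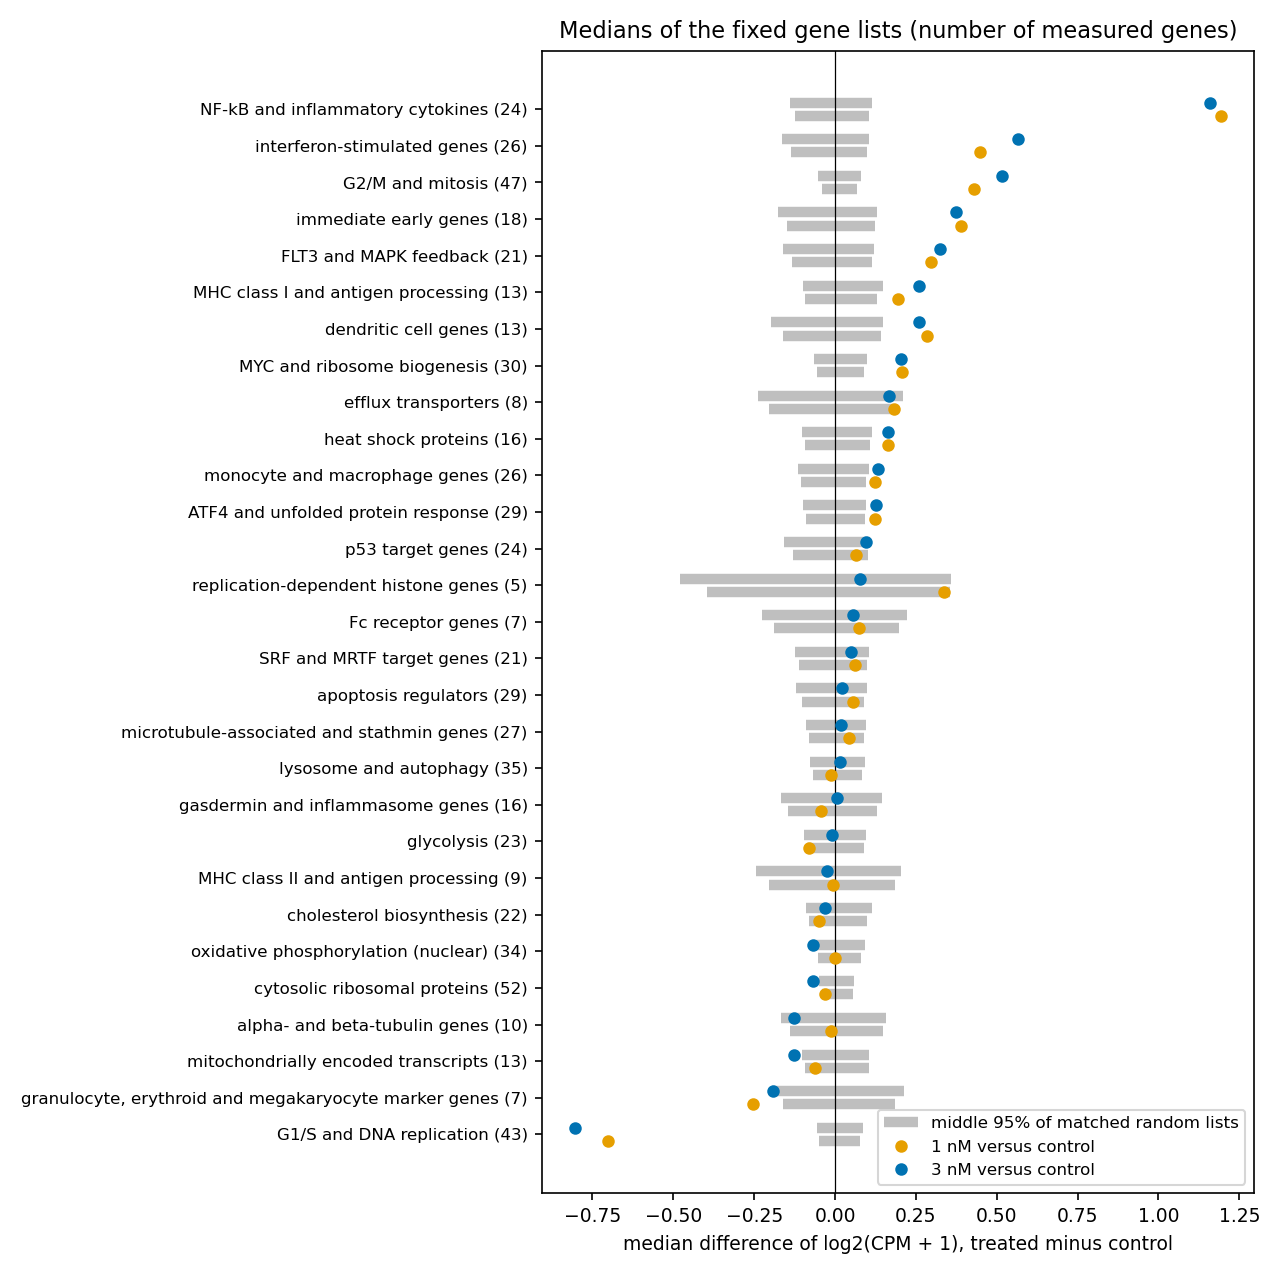
Median difference of log2(CPM + 1), treated minus control, of the 29 gene lists with at least 5 measured genes, at 1 nM and 3 nM, with grey bars for the middle 95% of 10000 expression-matched random lists. The G1/S list lies furthest below 0 (-0.70 and -0.80) and the NF-kB list furthest above it (1.19 and 1.16).

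The same genes recurred at both doses. Of the genes at least 2-fold higher, 75 were shared between 1 nM and 3 nM, where independent lists would share 0.822, and of those at least 2-fold lower, 18 were shared against 0.151. None of the genes was 2-fold apart in opposite directions (0 genes). Higher at 1 nM alone were 14 genes and at 3 nM alone 35, and lower 8 and 51. Across the 11908 genes, which are not independent replicates, the differences at the doses had a correlation of 0.875. Unchanged libraries against 1 shared control gave 0.478 with Poisson counts and 0.493 with an added variation of 10%, and shared 0 genes. The covariance was 0.0868, against 0.00596 and 0.0240 in these simulations, a difference of 0.0808 and 0.0627. With a single control library it could not be split, so part of the overlap may come from that library.

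**Figure D3:**
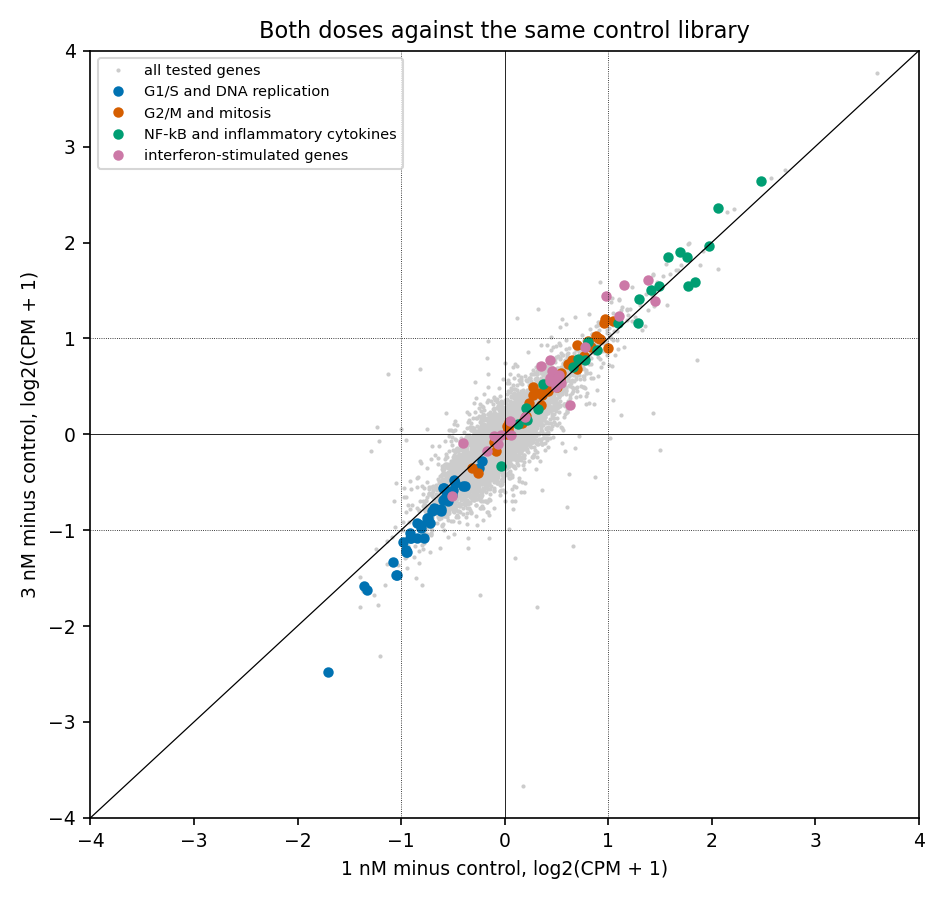
Difference of log2(CPM + 1) from the control at 1 nM (horizontal axis) and 3 nM (vertical axis) for 11908 genes, with 4 gene lists in colour, dotted lines at 2-fold and a solid line of equal values. Both axes share the control library. The correlation across genes was 0.875, and the 43 G1/S genes all lie below 0 on both axes.

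Between the doses the libraries differed less. Of 29 lists, 10 lay outside their ranges at 3 nM versus 1 nM, among them both cell-cycle lists. The G1/S genes had a median of -0.14 at 3 nM versus 1 nM, with 40 of 43 lower at the higher dose, below all 10000 random lists. The G2/M genes had a median of 0.07, above all 10000, and the interferon list one of 0.09, above its range. CCNE2 was 1.75-fold lower at 3 nM than at 1 nM (1.53 to 2.01), and FAM111B 2.63-fold lower (1.86 to 3.78).

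Of the other lists, the NF-kB median of 0.06 lay just above its range, with 14 of 24 members above 0. Tubulin genes had a median of -0.13, below the range, with 9 of 10 lower at 3 nM. After thinning to equal depth, which picks reads at random, the median was -0.06. Among members with high counts, TUBA1B had a ratio of 0.896 (0.879 to 0.912), TUBB 0.903 (0.882 to 0.924) and TUBB4B 0.979 (0.953 to 1.01). Ribosomal protein genes (-0.04, below all 10000 random lists), mitochondrially encoded transcripts (-0.05, with a mean of -0.12), nuclear oxidative phosphorylation genes (-0.05) and the 5 measured of 45 histone genes (-0.34) also lay below their ranges, and the granulocyte, erythroid and megakaryocyte list (0.10) above. In all 4 of the 29 lists lay above and 6 below, and the others inside their ranges. In simulated unchanged libraries with Poisson counts, 9 of these 10 medians lay beyond all 100 draws. With an added variation of 10% only 1 did, that of the G1/S genes. Over all genes the differences between the doses had a median absolute deviation of 0.0748, smaller than such added variation alone would give. A median within those draws is therefore not shown to be noise. Such draws leave out variation shared by the genes of a list, so they do not bound variation between cultures.

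Only 8 genes were at least 2-fold higher and 14 at least 2-fold lower at 3 nM than at 1 nM, 0 of them on a fixed list. The naming rule took FAM111B and RPL36A-HNRNPH2, the second a readthrough model at 2.97, 13.4 and 5.81 CPM whose reads are shared with its parts. In total 15 of the 22 genes were unnamed, readthrough models or parts of one. At a mean of at least 10 CPM, 0 genes were 2-fold apart in either direction.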

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

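The tests of transcript length, the simulated list medians and the thinning in this part were chosen after the differences between the doses were seen, and the other tests were planned before their results.

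MT-ATP8, a mitochondrially encoded subunit gene of ATP synthase, moved in opposite directions at the doses, with a log2 difference from the control of 0.07 at 1 nM and -0.45 at 3 nM (225, 236 and 165 CPM). Both counting intervals excluded a ratio of 1, the difference between the doses was not tested against culture variation, and the gene overlaps MT-ATP6, so that reads can be assigned to either.

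The 3 nM and 1 nM libraries differed by at least 2-fold in 22 genes and by smaller amounts in the medians of 10 lists outside their ranges. For the genes, counting noise was argued against, since simulated unchanged libraries gave a mean of 0.01 genes past 2-fold. For the lists noise stays open. With Poisson counts 9 of the 10 medians lay beyond 100 simulated draws. With an added variation of 10% only the G1/S median did (-0.14 against -0.104 to 0.111). That variation was larger than the libraries show, since over all genes the differences between the doses had a median absolute deviation of 0.0748. A median within those draws is therefore not shown to be noise. The tubulin median was -0.0596 after thinning, which picks reads at random, against a lower bound of -0.0716 for its random lists before thinning. Simulated draws of both kinds leave out variation shared by the genes of a list, so noise stays open for the G1/S median too. Transcript length, taken roughly as the median over the annotated transcripts of a gene, was argued against for 2 lists. Without the trends with length and GC content the ribosomal protein median was -0.0333 against -0.0370, and the G1/S median -0.14 as before. Read assignment between overlapping gene models stays a candidate explanation for the genes, since 68.2% of the 22 were unnamed, readthrough models or parts of one, against 3.02% of all genes examined, and a dose effect on others such as FAM111B stays open. Only 4 of the 8 higher and 9 of the 14 lower genes had a symbol. Unnamed genes were counted without a check that they overlap another gene model, so the share does not by itself show shared reads.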

How the results depend on the processing

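No paired analysis was possible because each group held 1 library. Thinning and the removal of length and GC trends were added after the data were seen. Of 8 gene counts, 278 single-gene differences and 87 list medians, all stayed the same under the library total and DESeq2 size factors. A gene count was taken as the same within a factor of 1.5, a list median within 1 SD of its random lists, and a single-gene difference within the half-width of its 95% counting interval on the log2 scale. A result was taken as reversed when a called value changed sign or came to 0, and otherwise as moved. Counts of genes are given in the order 1 nM higher and lower, 3 nM higher and lower, 3 nM versus 1 nM higher and lower, and both doses higher and lower, with main values of 89, 26, 110, 69, 8, 14, 75 and 18. A pseudocount of 0.1 gave 159, 73, 190, 164, 20, 40, 127 and 44, and a pseudocount of 5 gave 29, 8, 42, 29, 0, 1, 28 and 8. A mean of at least 10 gave 38, 9, 51, 34, 0, 0, 36 and 9, because fewer genes were examined, and 1.5-fold gave 336, 267, 421, 470, 31, 51, 282 and 198, by its wider rule. TPM gave 14 higher genes at 3 nM versus 1 nM, 5 of them shared with the main count, and the cause was not tested. Higher counts under small pseudocounts and lower ones under large pseudocounts follow from low-expressed genes, whose differences the pseudocount sets.

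Of the list medians that answer the comparisons, the tubulin median was -0.12 at 1 nM, -0.22 at 3 nM and -0.072 between the doses at a mean of at least 10. With TPM it was -0.0340 at 3 nM and -0.0622 between the doses, without a filter -0.0391 and -0.0325, and between the doses -0.0782 with a pseudocount of 5 and -0.0596 after thinning. The G2/M median between the doses was 0.0875 with TPM and 0.094 without length and GC trends. The G1/S mean was -0.74, -0.91 and -0.17 at 1 nM, 3 nM and between the doses, and the median between the doses was -0.12 with TPM. The NF-kB median at 1 nM and 3 nM was 1.28 and 1.23 with TPM, 1.38 and 1.36 with a pseudocount of 0.1, 0.73 and 0.73 with one of 5, 0.75 and 0.78 without a filter, and 1.42 and 1.51 at a mean of at least 10. At 1 nM it was 1.12 as a mean and 1.28 without length and GC trends. The interferon median was 0.53 at 1 nM with a pseudocount of 0.1, 0.26 and 0.34 with one of 5, 0.35 at 1 nM without a filter, and 0.13 and 0.16 at a mean of at least 10. Without a filter 3 medians that had been called came to 0.00, those of histone genes between the doses, and of granulocyte, erythroid and megakaryocyte markers at 1 nM and between the doses, because genes near 0 counts then entered. For the other changes of list medians the cause was not tested. Over all results and alternatives, 39 of the gene counts stayed and 33 moved, 1603 single-gene differences stayed and 65 moved with 0 reversed, and 765 list medians stayed, 99 moved and 3 reversed. Depth limits the values of low-expressed genes, since 3 counts stood for 0.144 to 0.169 CPM.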

Other observations

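The tests on RNA from other cells and on another component of the preparation, the thinning to equal depth, the removal of length and GC trends, the survey of annotated pathways, and the medians and simulated draws of repair genes on no fixed list were chosen after the differences between libraries were seen.

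Medians of 3 DNA repair pathways, picked from 291 after their values were seen, were lower than in the control, with members in both directions. Of the 291 KEGG pathways annotated in the table with 15 to 250 measured members, mismatch repair had medians of -0.32 and -0.38 at 1 nM and 3 nM, homologous recombination -0.22 and -0.30, and the Fanconi anemia pathway -0.22 and -0.28, each below all 10000 matched random lists. Among their members that stood on no fixed list, and chosen after their values were seen, the helicase gene BRIP1 had 68.4 CPM in the control, 30.6 CPM at 1 nM and 26.1 CPM at 3 nM, the end-resection gene RBBP8 65.8, 37.4 and 29.9 CPM, and the mismatch repair gene MSH6 194, 118 and 108 CPM. Without the genes of any fixed list the medians were -0.31 and -0.35 for 17 mismatch repair genes, -0.10 and -0.22 for 34 genes of homologous recombination and -0.19 and -0.26 for 44 Fanconi anemia genes, each below its range and below all 100 simulated unchanged draws with an added variation of 10%. Of all 76 such genes 21 were above 0 at 1 nM and 16 at 3 nM, and 1 and 3 were at least 2-fold lower. In homologous recombination 13 of 34 were above 0 at 1 nM. The simulated draws leave out variation shared between genes. These pathways share members with each other and with the G1/S list, and 22.7%, 12.8% and 8.33% of their genes stood on a fixed list.

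Complement and coagulation genes had medians of 0.16 and 0.17, above 99.9% of random lists, with the complement component gene C3 at 20.5, 68.96 and 72.2 CPM and PLAUR, the urokinase receptor gene, at 42.6, 94.7 and 108 CPM. Fatty acid metabolism had medians of -0.14 and -0.15 and the degradation of valine, leucine and isoleucine -0.14 and -0.17, each below all 10000 random lists, with 34 of 50 and 32 of 43 members below the control at 1 nM. Of the 291 pathways, 57 lay above and 31 below their range at 1 nM, 90 and 34 at 3 nM, and 36 and 18 at 3 nM versus 1 nM, where chance gives 7.275 on each side. Pathways overlap, so these counts are not independent, and even the treated libraries exceed that number between them. An unnamed gene, ENSG00000285238, had 244 and 272 counts in the control and 1 nM libraries and 0 at 3 nM, and ENSG00000289027 had 0, 226 and 224. The pathways and genes of this paragraph were chosen after their values were seen.

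G1/S genes were lower and G2/M genes higher than in the control at both doses. Depth and transcript composition were argued against as whole causes. The G1/S median at 3 nM was -0.81 after thinning and -0.80 after removing length and GC trends, and the G2/M median then 0.53. Thinning can move medians of CPM values little. The 1 nM library, with 20417769 counts against 20817408 in the control, had a G1/S median of -0.70. Removing length trends was a rough check, since length was the median over the annotated transcripts of a gene. Fewer cells in S phase stays a candidate explanation but cannot be told apart from lower expression of these genes per cell. The 101 annotated DNA replication genes on no fixed list had a median of -0.12, below all 10000 random lists. This met the bound set in advance for fewer cells in S phase, but either explanation would lower the median. It was far smaller than the -0.80 of the list, whose genes the set left out. More cells in mitosis cannot be told apart from higher expression per cell: 416 annotated mitosis genes on no fixed list had a median of 0.00036, inside the range, which met the bound set in advance against it, but that bound was judged wrong after the result was seen, because the set left out every listed G2/M gene. That blocked microtubule assembly holds cells in mitosis is a hypothesis for which cell counts or DNA content would be needed.

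NF-kB and cytokine genes were higher at both doses. Depth was argued against by a median of 1.16 after thinning and by one of 1.19 at 1 nM, where depth was close to the control. RNA from other blood or tissue cells was argued against for the cell types of the marker lists. The median over lists of 20, 23 and 15 marker genes was 0.0122 CPM in the treated libraries. RNA from a single cell type could leave this pooled median low, but single markers of other cells were low too. The highest treated values were 7.89 CPM (NKG7, 6.28 CPM in the control) in the lymphoid list and 1.32 CPM (PDGFRB) in the epithelial and fibroblast list. The highest in the granulocyte, erythroid and megakaryocyte list, PRTN3 (438 CPM) and CTSG, are genes these cells express themselves. Of the 7 measured members of that list, 6 were below the control at each dose. Cell types without a listed marker are not covered. One inflammatory response that also includes interferon genes stays open: 61 annotated TNF signaling genes on no fixed list had a median of 0.038, inside the range, and here too the bound set in advance against it was met and then judged wrong after the result, since the set left out the listed genes. Another component of the preparation, such as the FL part, the Fc part or an impurity, cannot be told apart from DM1. No library had the preparation without DM1, and the difference of 0.0565 in the list median between the doses does not decide.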
